A study of Mus musculus with 8 samples.

How the data were processed

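Stranded polyA RNA sequencing libraries came from mouse embryonic stem cells that carried a MERVL::EGFP reporter and were transfected with siRNA on consecutive days. Per the labels, the 8 libraries fall into 4 groups of 2 biological replicates: negative control siRNA, siRNA against Chaf1a with negative control siRNA, siRNA against Chaf1a with the diced pool si308, and siRNA against Chaf1a with the diced pool si309. Both pools target mDux and were made by dicing double-stranded RNA with Giardia Dicer. The label of 1 library with si309 gives no dose. Reads were 125 bases, paired, from a HiSeq 2500.

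The authors aligned reads with Novoalign 2.8 to mm10 and used DESeq2, per the labels; the read counter, its annotation and the DESeq2 version are not stated in the sources used. The deposited tables hold raw counts per Ensembl gene and per repeat name for each library. Beside the counts, the deposited tables give regularised log2 values per library and log2 fold changes against the negative control. The authors also gave an adjusted p-value for each comparison with the negative control, and none for some genes. Count columns are numbered 0 and 1 within a group, and they were mapped to groups, not to single labels, so replicate 0 and replicate 1 name the columns.

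The gene table held 28431 genes, of which 27843 IDs matched GENCODE release 21 for mouse, the source of the GRCm38 coordinates. Date-like names stood in place of 27 symbols, so genes were matched by ID. The symbol Atf7ip stood at 2 IDs, so the list that holds it has 34 members and 35 tested genes. mDux is listed under the symbol 4933403O03Rik, which GENCODE names Duxf3. The primers given with the study were matched exactly to its transcripts and to the other transcripts of the annotation to place the fragments behind the pools.

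Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with the groups, which left 17977, and were scaled with TMM factors. The model had 1 mean per group and 4 residual degrees of freedom over the 8 libraries, and contrasts were tested with edgeR's quasi-likelihood F test, without robust estimation. The common dispersion was 0.00196 and the prior degrees of freedom for genes were 17.1. P-values were adjusted by Benjamini and Hochberg over all genes tested in a contrast, and raised and lowered mean an adjusted p under 0.05. Repeat names (1499 in the table, 1253 tested) were fitted in the same way with library sizes and TMM factors from the gene table, and the smallest adjusted p-values are listed as 0. With 4 residual degrees of freedom, repeat p-values this small rest largely on a spread shared over repeats. They do not measure the spread of each repeat between libraries. CPM values used the TMM factors, and errors after ± are standard deviations of 2 libraries.

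The contrasts were Chaf1a siRNA minus negative control, each pool with Chaf1a siRNA minus Chaf1a siRNA with negative control siRNA, the difference between the pools, and each pool with Chaf1a siRNA minus negative control. The counts of Chaf1a-raised genes lowered by the pools were set beside 20 simulations in which the pool groups had the means of the Chaf1a group, since these comparisons share libraries.

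The gene lists, written by hand from general knowledge, numbered 16: two-cell-like genes, CAF-1 and histone chaperones, naive pluripotency, repressors of retroelements and of the two-cell-like state, primitive endoderm, trophectoderm, postimplantation and germ layers, fibroblast, germline, p53 response, interferon and double-stranded RNA response, S phase, G2/M phase, integrated stress response, imprinted and reference genes. The repeat lists numbered 9: MERVL, other MT2 elements, MaLR, IAP, ETn and MusD, other ERV1 and ERVK elements, L1, SINE and satellite. Gene lists were tested with camera of limma 3.58.1, with a preset correlation between genes of 0.01 and with an estimated correlation, adjusted over lists within a contrast; fry served as a self-contained test. Repeat lists were described by counts.

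Named genes followed a rule: Chaf1a and mDux; for each of the contrasts on Chaf1a depletion and on the pools, up to 10 raised and 10 lowered genes with the largest fitted fold change among those with an adjusted p under 0.05, a mean of at least 1 CPM in the higher group, separated libraries and no predicted-model name; and up to 4 members per list with the smallest adjusted p. For repeats the rule took MERVL-int, MT2_Mm, up to 8 raised and up to 5 lowered names. The groups, the tests, the lists, the alternatives and this rule were chosen before the data were examined, except where a part says otherwise.

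Library totals were 26042851 to 42375685 counts for genes and 1746498 to 2945624 for repeats. A fold against a group with no counts is given as a lower bound from a floor of 3 counts per library, and a ratio against 1 to 3 counts is given with its exact 95% counting interval. Reads carried no molecular identifiers, so intervals and floors cover counting error only. Gene names of receptor families and of repeats do not separate reads shared between copies, and the treatment of such reads is unknown.

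The tests were checked on simulated data with the spread of these libraries. Among 200 changed genes, edgeR called 74% of those changed by 1 on the log2 scale and 93% of those changed by 2, and DESeq2 1.42.0 called 69% and 86%. EdgeR also called 11 unchanged genes, 6.2% of its calls. Among 60 changed repeats the shares were 83.3% and 93.3% with edgeR and 73.3% and 83.3% with DESeq2, and edgeR called 4 unchanged repeats, 7% of its calls. Far fewer genes and repeats were changed in the simulations than were called with Chaf1a siRNA, so these shares may not carry over to the data.

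Alternatives were DESeq2's Wald test, RLE scaling, no low-count filter, a minimum fold of 2, fits of 2 groups only, a replicate block, repeat scaling by the repeat table, an estimated correlation in camera, and leaving out each library in turn. A minimum mean of 1 CPM, scaling by library totals and a test of gene families within strata of level were added after the data were seen. The authors' regularised log2 values were not used, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.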

Results

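PolyA RNA was sequenced from mouse embryonic stem cells grown with 2i and serum, a culture in which a small share of cells enters a state resembling the embryo at the cleavage stage. CHAF1A is the large subunit of the histone chaperone CAF-1, and DUX is a double homeobox transcription factor of early embryos. The series compared 20 pmol of negative control siRNA, 10 pmol of Chaf1a siRNA with 10 pmol of negative control siRNA (called Chaf1a siRNA here), and 10 pmol of Chaf1a siRNA with 10 pmol of 1 of 2 diced siRNA pools against mDux (si308 and si309). Each of the 4 groups had 2 replicates, and the label of 1 library with si309 gives no dose. Gene counts were 27937053 and 35845976 in the negative control libraries, 33942345 and 26042851 with Chaf1a siRNA, 30320146 and 42375685 with si308, and 30376942 and 38179797 with si309. Repeat counts per 100 gene counts were 6.35 ± 0.141 in the negative control, 8.6 ± 0.212 with Chaf1a siRNA, 7.325 ± 0.53 with si308 and 6.92 ± 0.0283 with si309.

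Chaf1a (ENSMUSG00000002835, GRCm38 chromosome 17, 56040439 to 56072289) was measured first, to see how far each siRNA mix lowered its target. Chaf1a RNA was 139 ± 0.65 CPM in the negative control and 29.6 ± 1.5 CPM with Chaf1a siRNA, a 4.72-fold decrease (log2 change -2.24, SE 0.07, adjusted p = 3.4e-17). It was 34.6 ± 0.84 CPM with si308 and 31.5 ± 3.1 CPM with si309, or 24.9% and 22.6% of the negative control. Chaf1a was thus higher with si308 than in the Chaf1a siRNA group (0.23, SE 0.07, adjusted p = 0.025), a call that was lost without Chaf1a siRNA replicate 0 (adjusted p = 0.22), si308 replicate 0 (0.11) or si308 replicate 1 (0.052). The difference was 0.09 with si309 (SE 0.07, adjusted p = 0.51) and -0.14 between the pools (SE 0.07, adjusted p = 0.34).

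mDux is a multi-copy gene. The copy followed here as mDux, 4933403O03Rik or Duxf3 (ENSMUSG00000075046, chromosome 10, 58229979 to 58232675, minus strand), had 0 and 2 counts in the negative control libraries and 256 and 193 with Chaf1a siRNA. Its mean rose from 0.0303 ± 0.043 to 7.27 ± 0.085 CPM (ratio 213, 95% counting interval 58.6 to 1760; log2 change 7.58, SE 0.43, adjusted p = 1.7e-12). With si308 mDux RNA fell to 0.0623 ± 0.043 CPM, 103-fold below the Chaf1a siRNA group (-6.68, SE 0.37, adjusted p = 3.6e-12). With si309 it fell to 0.193 ± 0.049 CPM, 36.3-fold below the Chaf1a siRNA group (-5.18, SE 0.31, adjusted p = 2.1e-11). Against the negative control the ratio was 1.96 with si308 (0.321 to 20.6, adjusted p = 0.49) and 5.77 with si309 (1.33 to 52.3, adjusted p = 0.019). The latter call was lost without negative control replicate 0 or si309 replicate 1 (adjusted p = 0.11 in each). Between the pools the ratio was 2.94 (1 to 10.4; exact binomial p = 0.038; quasi-likelihood p = 0.043, adjusted p = 0.29).

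**Figure D1:**
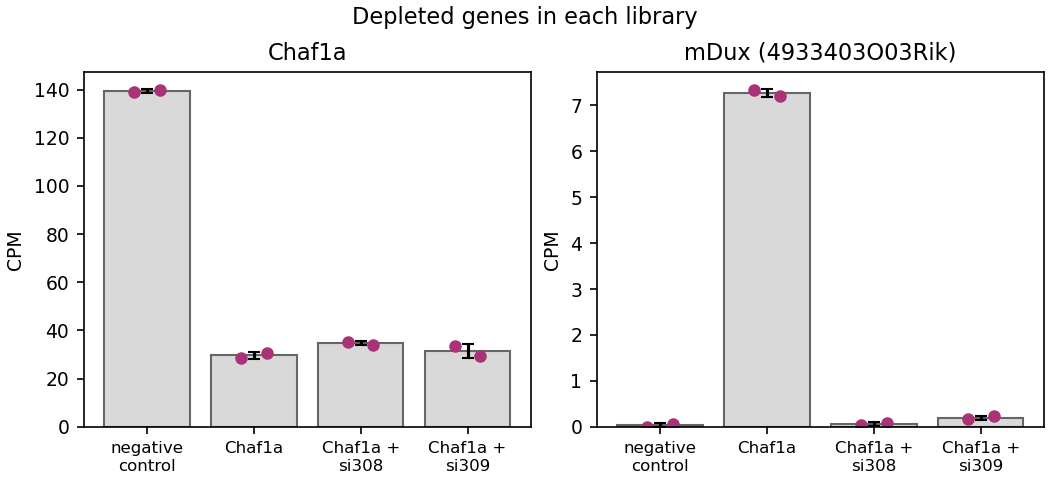
RNA of Chaf1a and mDux (4933403O03Rik) in CPM on the vertical axes for the 4 groups; bars are means, error bars SD and points the 2 libraries. Chaf1a stands at 139 CPM in the negative control and at 29.6 to 34.6 CPM in the other groups, and mDux at 7.27 CPM with Chaf1a siRNA and under 0.2 CPM elsewhere.

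The fragments used for the pools lay in a single-exon Duxf3 transcript of 2025 bases, wholly in its coding sequence. The other protein-coding transcript of Duxf3 matched only 1 primer of each pair. The si308 fragment of 408 bp spans 58231220 to 58231627, and the si309 fragment of 480 bp spans 58230694 to 58231173. The si309 primers also matched the pseudogene Gm10807 in the same array (58227900 to 58228379). Summed over both libraries, Gm10807 had 0 counts in the negative control, 161 with Chaf1a siRNA, 0 with si308 and 2 with si309, and the array copy AW822073 had 1, 280, 2 and 9. How reads were divided among copies is unknown.

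**Figure D2:**
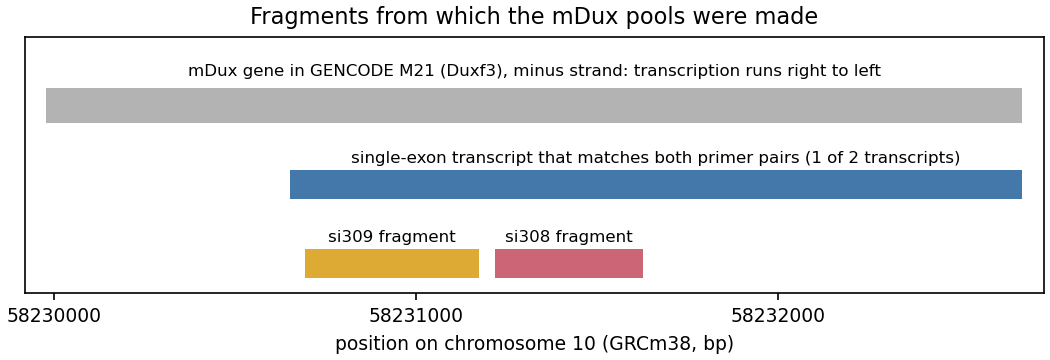
Map of the Duxf3 gene on GRCm38 chromosome 10 (horizontal axis, position in bases), with the gene, the single-exon transcript that matches both primer pairs and the fragments diced for each pool drawn to scale. The si308 fragment (408 bp) and the si309 fragment (480 bp) do not overlap.

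Chaf1a siRNA against the negative control asks what changes when CAF-1 is depleted. The clearest change was in genes of the two-cell-like state, such as the Zscan4 and Usp17l clusters, which are normally transcribed in the early embryo. Zscan4d (chromosome 7, 11161374 to 11166159) rose 479-fold, from 0.525 ± 0.24 to 264 ± 12 CPM (log2 change 8.90, SE 0.12, adjusted p = 1e-22). Usp17lb (chromosome 7, 104840257 to 104842603) rose 1920-fold to 171 ± 5.1 CPM (10.91, SE 0.16, adjusted p = 1.2e-22), and Usp17la rose 848-fold to 163 ± 2.6 CPM. Zfp352 rose to 33.3 ± 0.17 CPM, a ratio of 1950 (349 to 77000), and Tdpoz4 to 28.2 ± 1.4 CPM, a ratio of 1640 (295 to 65000). Of the list of 57 two-cell-like genes, 47 were tested and 47 rose (47 adjusted over the list alone), with a median of 8.62, or 8.48 with the 6 genes without counts in the negative control at their bound. This list passed camera (adjusted p = 1.3e-21, and adjusted p = 0.0046 with an estimated correlation).

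Outside that list, Dnmt3l, a cofactor of DNA methylation, rose from 107 ± 4.3 to 545 ± 5.2 CPM (2.36, SE 0.06, adjusted p = 1.3e-18), and the testis gene Tex101 rose 103-fold to 106 ± 3.1 CPM (6.69, SE 0.10, adjusted p = 2e-22). The largest rises by the naming rule included D13Ertd608e (at least 108-fold higher), Pramef6 (100), Ankrd22 (88.5), Phf11a (77.8), Hdc (54.5), Adh7 (52.2) and Mrgprx2 (49.9), each with no counts in the negative control. The largest falls were of Tlx1 (-3.98, SE 0.60), Setbp1 (-2.71, SE 0.32), Elavl4 (-2.66, SE 0.43) and Nkx6-3 (-2.52, SE 0.42). Arhgef38 dropped from 18.8 ± 0.95 to 3.29 ± 0.05 CPM (-2.51, SE 0.13, adjusted p = 5.1e-13). Fgf17, Rasgrp1, Hesx1, Zfp2 and Pycr1 fell 4.85-fold to 5.66-fold.

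Lists of lineage, germline, imprinted and pluripotency genes were compared next, and none of these passed camera with an estimated correlation. With the preset 0.01, fibroblast (adjusted p = 2.9e-06), germline (5.3e-06), imprinted (8.2e-06), primitive endoderm (0.0012) and naive pluripotency genes (0.011) passed. Trophectoderm (0.13) and postimplantation genes (0.85) did not. Fry gave adjusted p = 0.0096 or lower for each list. The correlations estimated for fibroblast (0.007), primitive endoderm (-0.044) and naive pluripotency genes (-0.034) were below the preset, so correlation alone does not account for their lost calls. Fibroblast genes included Thy1 (1.31 to 28.3 CPM, log2 change 4.41, SE 0.13) and Col1a2 (0.128 to 16.1 CPM, log2 change 7.02, SE 0.28), and 15 of 16 rose and 1 fell (15 and 1 adjusted over the list alone, median 4.07, or 3.41 with bounds, adjusted p = 0.053 with an estimated correlation). Primitive endoderm genes rose in 14 of 18 cases and fell in 2 (14 and 2 adjusted over the list alone, median 2.51, or 2.03 with bounds, adjusted p = 0.081 with an estimated correlation), among them Col4a1 (37.5 to 227 CPM) and Dab2 (1.24 to 17.6 CPM). Germline genes rose in 18 of 23 cases and fell in 2 (20 and 2 adjusted over the list alone, median 1.92, adjusted p = 0.19 with an estimated correlation), with Taf7l at 126 ± 8.2 and Dazl at 207 ± 11 CPM. Imprinted genes rose in 18 of 23 cases and fell in 3 (19 and 3 adjusted over the list alone, median 1.07, adjusted p = 0.081 with an estimated correlation), including Peg10 (101 to 414 CPM) and H19 (7.22 to 53.4 CPM). Trophectoderm genes rose in 10 of 16 cases and fell in 5 (10 and 5 adjusted over the list alone, median 0.98, adjusted p = 0.36 with an estimated correlation), Krt8 among the former (2.81 to 14.3 CPM). Postimplantation genes rose in 9 and fell in 5 of 16 cases (9 and 6 adjusted over the list alone, median 0.69, adjusted p = 0.86 with an estimated correlation), and Lefty1 fell 4.27-fold. Naive pluripotency genes fell in 15 of 25 cases and rose in 7 (15 and 7 adjusted over the list alone, median -0.27, adjusted p = 0.12 with an estimated correlation), led by Fgf4 (280 to 88.0 CPM, log2 change -1.67, SE 0.06, adjusted p = 9.8e-16) and Tcl1 (124 to 44.4 CPM).

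Among the other lists, p53 response genes rose in 15 of 24 cases and fell in 5 (15 and 5 adjusted over the list alone, median 0.50, adjusted p = 0.2 with an estimated correlation). Plk2 rose from 58.1 to 218 CPM and Perp from 6.78 to 50.1 CPM. Interferon response genes rose in 14 of 24 and fell in 5 (14 and 5 adjusted over the list alone, median 0.68, adjusted p = 0.25 with an estimated correlation). Among the latter, Ifitm3 fell 2.58-fold. S phase genes such as Mcm6 (860 to 544 CPM) fell in 18 of 24 cases and rose in 3 (18 and 3 adjusted over the list alone, median -0.28, adjusted p = 0.26 with an estimated correlation). G2/M genes fell in 12 of 23 cases and rose in 4 (12 and 4 adjusted over the list alone), and their median of -0.11 became 0.05 with library totals in place of TMM factors (adjusted p = 0.36 with an estimated correlation). Integrated stress response genes, Atf4 among them (281 to 149 CPM), fell in 12 of 21 cases and rose in 6 (12 and 6 adjusted over the list alone, median -0.34, adjusted p = 0.37 with an estimated correlation). CAF-1 and histone chaperone genes fell in 12 of 21 and rose in 7 (12 and 7 adjusted over the list alone, median -0.21, adjusted p = 0.26 with an estimated correlation), and Npm1 fell from 6170 to 3900 CPM. Repressors of retroelements fell in 20 of 35 and rose in 9 (21 and 9 adjusted over the list alone, median -0.26, adjusted p = 0.26 with an estimated correlation). Reference genes fell in 8 of 16 and rose in 3 (8 and 3 adjusted over the list alone, median -0.25, adjusted p = 0.26 with an estimated correlation), Rpl13a by 1.77-fold. With library totals the medians of the other lists that lie below 0 moved closer to it: -0.04 for chaperones, -0.11 for naive pluripotency, -0.12 for S phase, -0.18 for the stress response, -0.10 for repressors and -0.09 for reference genes. With the preset correlation camera called 12 of the 16 lists, and only the two-cell-like list with an estimated one. Some lists that lost their call had an estimated correlation below the preset, so the loss does not measure correlation alone.

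**Figure D3:**
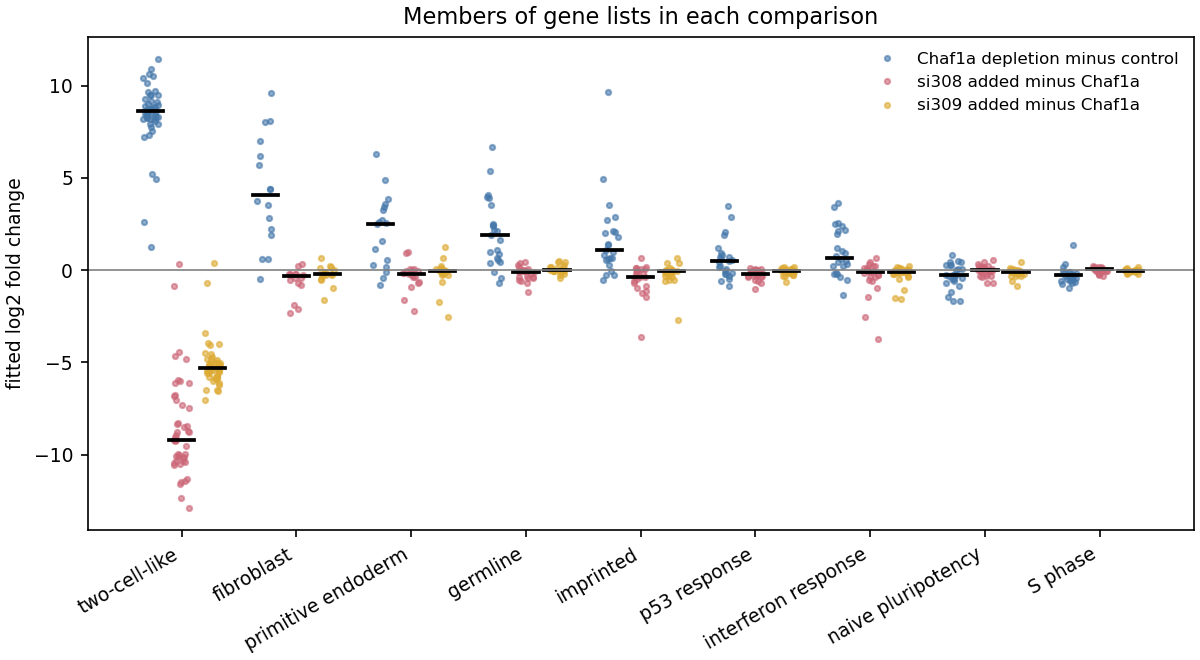
Log2 fold change of each tested gene (points) of 9 gene lists for Chaf1a siRNA against the negative control and for each pool against the Chaf1a siRNA group; black bars are medians. The two-cell-like median is 8.62 in the first comparison, -9.18 with si308 and -5.29 with si309.

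Over all genes, edgeR's quasi-likelihood test called 6597 raised and 5545 lowered by Chaf1a siRNA at a BH-adjusted p under 0.05, and 3867 and 667 of them changed at least 2-fold. Of 1254 genes under 0.1 CPM in the negative control, 1199 rose at least 2-fold and 0 fell so far, but such genes pass the filter only through counts in other groups and have little room to fall. Of 3439 genes at 0.1 to 1 CPM, 1526 rose and 102 fell at least 2-fold, and those at the low end can pass the filter in the same way. Of 4025 genes at 1 to 10 CPM, 905 rose and 259 fell at least 2-fold, of 6553 genes at 10 to 100 CPM 229 and 249, and of 2706 genes over 100 CPM 8 and 57. Library totals in place of TMM factors gave 8128 raised and 3788 lowered genes. They moved the median of all genes from 0.05 to 0.22, and small folds are relative to that choice. The adjusted values in the authors' deposited table list 5623 genes as raised and 5318 as lowered. At least 2-fold they list 2409 and 421, fewer than the 3867 and 667 of the refit. The authors' fold changes correlated with the refitted ones across genes (Spearman 0.98), which are not independent replicates.

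The comparison of si308 with the Chaf1a siRNA group asks what changes when the negative control siRNA beside Chaf1a siRNA is replaced by a pool against mDux. Two-cell-like genes went back to levels near the negative control. Zscan4d fell from 264 ± 12 to 0.219 ± 0.083 CPM (1140-fold, log2 change -10.15, SE 0.13, adjusted p = 3.1e-23), and Zscan4f fell 1410-fold. Tdpoz4 was at least 342-fold lower and Tdpoz3 at least 235-fold lower. D13Ertd608e, Pramef6, Spz1 and Mrgprx2 were at least 136, 126, 118 and 62.9-fold lower, and ratios were 1430 for Zscan4b (490 to 6960) and 1460 for Tmem92 (404 to 12100). Of 47 genes of the list 46 fell (46 adjusted over the list alone), with a median of -9.18, or -8.26 with the 11 genes at 0 in a group at their bound (adjusted p = 0.00038 with an estimated correlation). The exception was Chit1 (0.33, adjusted p = 0.34).

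Other lists moved less with si308. Peg10 fell from 414 ± 20 to 179 ± 17 CPM (-1.21, SE 0.06, adjusted p = 1.2e-13), and 11 of 23 imprinted genes fell and 2 rose (14 and 2 adjusted over the list alone, median -0.35, adjusted p = 0.1 with an estimated correlation). Of p53 response genes 11 of 24 fell (14 adjusted over the list alone, median -0.18, adjusted p = 0.095 with an estimated correlation). Among them, Pmaip1 fell from 60.1 ± 2 to 29.1 ± 3 CPM. Fibroblast genes fell in 10 of 16 cases and rose in 1 (10 and 1 adjusted over the list alone, median -0.34, adjusted p = 0.095 with an estimated correlation), Col1a2 to 4.33 ± 0.88 CPM (-1.87, SE 0.15). Primitive endoderm genes fell in 8 of 18 cases (8 fell and 1 rose adjusted over the list alone, median -0.20, adjusted p = 0.12 with an estimated correlation), Sox17 by -2.19 (SE 0.37). Germline genes fell in 7 of 23 and rose in 2 (7 and 2 adjusted over the list alone, median -0.11), and Dazl fell by 0.67 on the log2 scale. Interferon genes fell in 5 of 24 and rose in 3 (5 and 3 adjusted over the list alone, median -0.10), Irf7 by -2.52 (SE 0.36). Naive pluripotency genes rose in 6 and fell in 7 of 25 cases (7 and 8 adjusted over the list alone, median 0), with Lin28a raised by 0.57 and Nr0b1 lowered (-0.67).

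The remaining lists showed medians near 0 with si308: trophectoderm 0.03 (3 raised, 2 lowered), postimplantation -0.17 (1 raised, 2 lowered), S phase 0.04 (3 raised, 4 lowered) and G2/M -0.02 (2 raised, 4 lowered). Medians were -0.02 for chaperones (1 raised, 3 lowered), 0.05 for reference genes (1 raised, 1 lowered), 0.02 for the stress response (4 raised, 4 lowered) and 0 for retroelement repressors (5 raised, 5 lowered). Adjusted over the list alone the counts were the same except for 3 raised G2/M genes, 5 lowered stress response genes and 6 raised repressors. Camera's direction for the repressors and the stress response was up while their means were -0.02 and -0.03. Krt7, a keratin of trophectoderm, rose from 3.61 to 8.85 CPM (1.29, SE 0.16, adjusted p = 4.4e-06), and Sncb was raised by 1.49 (SE 0.30, adjusted p = 0.0011). Other rises that the rule named lost their call in at least 1 fit without a library: Asb9 (1.99) and Ccm2l (1.74) without Chaf1a siRNA replicate 0 (adjusted p = 0.068 and 0.051), Ttll8 (1.66) without si308 replicate 0 (0.1), and likewise Kpna7, Cd3d, Rab17, Icam2 and Nkx6-3.

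In total 1782 genes rose and 2156 fell with si308, and 83 and 750 of these changed at least 2-fold. The count of raised genes was 1060 without Chaf1a siRNA replicate 0, 798 without Chaf1a siRNA replicate 1 and 1094 without si308 replicate 0, and the count of lowered genes was 1432 without Chaf1a siRNA replicate 1.

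The pool si309 repeats the question with siRNAs from another part of mDux. Zscan4d fell from 264 ± 12 to 5.63 ± 0.076 CPM (46.9-fold, log2 change -5.55, SE 0.08, adjusted p = 9.3e-22) and Zscan4c from 163 ± 5.6 to 3.78 ± 0.62 CPM (43.4-fold). Zscan4b, Pramef6, Apol7b and Zscan4e fell 92.7, 89.6, 68.9 and 68.7-fold. Of the two-cell-like list 46 of 47 fell (46 adjusted over the list alone, median -5.29, adjusted p = 0.00032 with an estimated correlation), Chit1 again being the exception (0.39, adjusted p = 0.32). Genes left with 1 to 3 counts were Ccl3 (ratio 76.5, 20.8 to 638), Obox2 (74.8, 20.3 to 624), Vmn2r52 (96.6, 16.9 to 3860), Olfr881 and Zswim2 (82.8 each, 14.4 to 3320).

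Imprinted genes fell in 6 of 23 cases and rose in 1 with si309 (7 and 2 adjusted over the list alone, median -0.06, adjusted p = 0.27 with an estimated correlation), Peg10 by -0.54 (SE 0.05, adjusted p = 1.5e-07). P53 response genes fell in 6 of 24 cases (6 adjusted over the list alone, median -0.04), fibroblast genes in 5 of 16 (5 fell and 1 rose adjusted over the list alone, median -0.20), primitive endoderm genes in 4 of 18 (5 fell and 1 rose adjusted over the list alone, median -0.07) and interferon genes in 4 of 24 (4 adjusted over the list alone, median -0.08). Col1a2 stood at 8.25 ± 0.55 CPM (-0.96, SE 0.14) and Pmaip1 at 39.0 ± 1.5 CPM (-0.63, SE 0.08). Naive pluripotency genes fell in 7 of 25 cases and rose in 1 (8 and 2 adjusted over the list alone, median -0.08, adjusted p = 0.17 with an estimated correlation), Nr0b1 by -0.85 (SE 0.09). Trophectoderm genes rose in 5 of 16 cases (6 rose and 1 fell adjusted over the list alone, median 0.18, adjusted p = 0.27 with an estimated correlation), Krt19 from 19.6 ± 2.2 to 35.8 ± 2.8 CPM (0.87, SE 0.11). Medians of the other lists were 0 for germline (2 raised, 2 lowered), 0 for G2/M (1 raised, 1 lowered), -0.03 for S phase (2 lowered) and 0.03 for stress response (4 raised, 3 lowered). They were -0.01 for chaperones (3 lowered), -0.01 for retroelement repressors (4 lowered), -0.06 for postimplantation (1 raised, 2 lowered) and -0.01 for reference genes (2 raised, 1 lowered), whose camera direction was up. Adjusted over the list alone these counts were the same except for 3 raised germline, 0 lowered G2/M and 4 lowered postimplantation genes.

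Wfdc1 (1.76, SE 0.25, adjusted p = 3e-05), Card9 (1.40, SE 0.27), Krt7 (1.24, SE 0.17) and Lgals7 (1.11, SE 0.23) were the rises named by the rule that kept their call in every fit without a library. Cd3d (1.64) lost it without Chaf1a siRNA replicate 0 (adjusted p = 0.11), and Rab17, Sncb, Myo7b, Ren1 and Fsd2 lost it in at least 1 such fit. In total 676 genes rose and 1269 fell, and 29 and 544 changed at least 2-fold. The count of raised genes was 420 without Chaf1a siRNA replicate 0, 215 without Chaf1a siRNA replicate 1, 354 without si309 replicate 0 and 196 without si309 replicate 1. The count of lowered genes was 741 without Chaf1a siRNA replicate 1 and 695 without si309 replicate 1.

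How far the pools undid the rise after Chaf1a depletion was asked over all 6597 raised genes. Of these si308 lowered 1753, si309 lowered 988, both pools lowered 926 and 4782 were lowered by neither, while 306 and 223 rose further. The median change of the raised genes was -0.139 with si308 and -0.06 with si309, against a simulated -0.01 for each without an effect of the pools. The si309 median was -0.095 without Chaf1a siRNA replicate 0, and -0.035 both with library totals and with a minimum mean of 1 CPM. Since these comparisons share the Chaf1a siRNA libraries, 20 simulations with no effect of the pools were run: at most 0 of the raised genes were lowered by both pools, at most 0 by si308 and at most 2 by si309. With no gene changed, adjusted p-values pass far less often than in the data. Overlap that sharing adds beside effects of the pools was therefore not measured. The count for si309 was 651 without Chaf1a siRNA replicate 1 and 618 without si309 replicate 1, and the count for both pools was 612 and 602. Among the 3867 genes raised at least 2-fold, 710 were lowered at least 2-fold by si308, 526 by si309 and 501 by both.

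**Figure D4:**
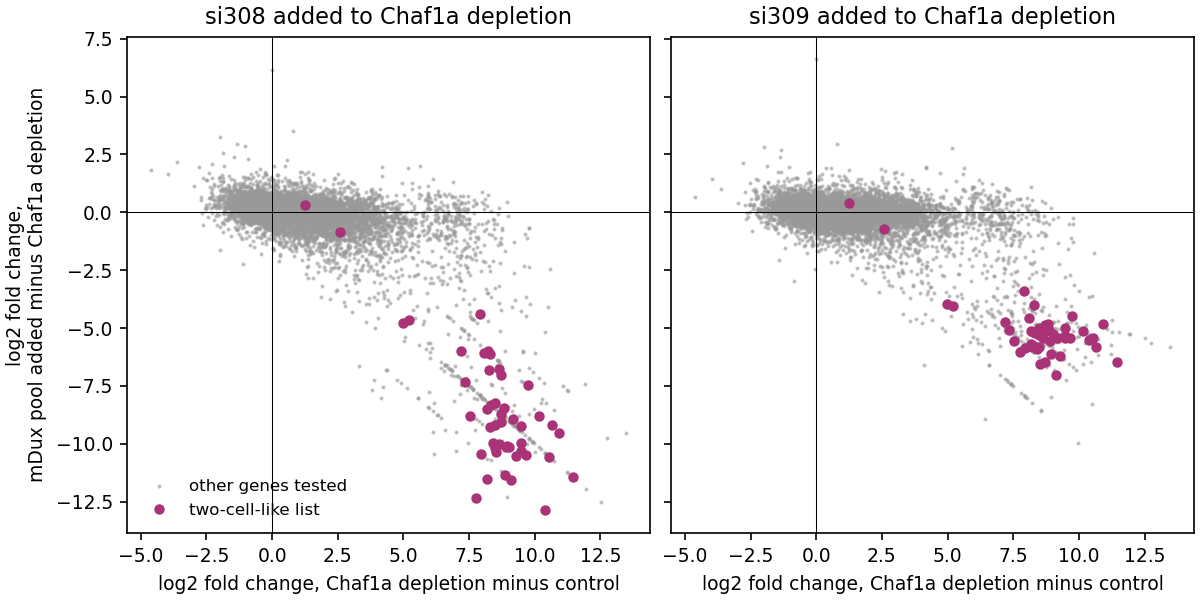
Log2 fold change of each tested gene with Chaf1a siRNA against the negative control (horizontal axis) and with si308 or si309 against the Chaf1a siRNA group (vertical axes); purple points are the two-cell-like list. Purple points lie far below 0 with both pools (medians -9.18 and -5.29), whereas the median of all Chaf1a-raised genes is -0.139 and -0.06.

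The groups with both targets depleted were also set against the negative control, a comparison that uses no Chaf1a siRNA library. Zscan4d stood at 0.219 CPM with si308, against 0.525 CPM in the negative control, and at 5.63 CPM with si309. Of the two-cell-like list 8 genes were above and 4 below the negative control with si308 (7 and 3 adjusted over the list alone), with a median of 0, a mean of -0.15 and a median with bounds of 0.23 (camera adjusted p = 0.94 with an estimated correlation). Of its 47 genes, 18 had at most 3 counts in each library of both groups and were left out of the median with bounds. For these 18 a return to the control level could not be measured. With si309 41 genes of the list were above the negative control and 0 below, 6 not passing edgeR's test (41 adjusted over the list alone, median 3.23, or 3.21 with bounds, camera adjusted p = 0.026 with an estimated correlation). Fibroblast genes stayed above in 15 and below in 1 of 16 cases with each pool (15 and 1 adjusted over the list alone, medians with bounds 2.77 and 3.22, adjusted p = 0.1 and 0.053 with an estimated correlation). Germline genes were above in 20 and below in 2 of 23 (20 and 2 adjusted over the list alone, medians 1.36 and 1.58, adjusted p = 0.18 and 0.15 with an estimated correlation). Genes raised at least 2-fold by Chaf1a depletion outside the two-cell-like list kept a median of 88.6% of their log2 rise with si308 and 95.2% with si309, shares that do rest on the Chaf1a siRNA libraries. In 20 simulations without an effect of the pools, genes chosen in this way kept 99.5% (99.1% to 99.8%) and 99.4% (99% to 99.7%). In total 5948 genes were higher and 5119 lower with si308, and 6299 and 5450 with si309.

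The pools were compared directly to test whether they acted alike. Two-cell-like RNAs were higher with si309 than with si308: Usp17lb was at 6.05 ± 0.61 against 0.232 ± 0.034 CPM (26.3-fold, log2 change 4.71, SE 0.21, adjusted p = 6.8e-12), and Zscan4d at 5.63 ± 0.076 against 0.219 ± 0.083 CPM (4.60, SE 0.23, adjusted p = 1.6e-11). Of the list 31 of 47 were higher and 0 lower (39 higher adjusted over the list alone, median 3.65, or 3.24 with bounds, adjusted p = 0.00059 with an estimated correlation). P53 response genes were higher in 9 of 24 cases (12 adjusted over the list alone, median 0.17, adjusted p = 0.054 with an estimated correlation). Imprinted genes were higher in 7 and lower in 1 of 23 cases (10 and 1 adjusted over the list alone, median 0.26, adjusted p = 0.074 with an estimated correlation), Peg10 by 0.66 (SE 0.06, adjusted p = 6.4e-08). Fibroblast genes were higher in 3 cases (5 adjusted over the list alone, median 0.28, adjusted p = 0.077 with an estimated correlation), and germline genes in 5 (8 adjusted over the list alone, median 0.19, adjusted p = 0.21 with an estimated correlation). Primitive endoderm and trophectoderm genes were higher in 2 cases each (3 each adjusted over the list alone, medians 0.17 and 0.29; adjusted p = 0.19 and 0.21 with an estimated correlation). Naive pluripotency genes were lower in 5 and higher in 1 of 25 cases (5 and 1 adjusted over the list alone, median -0.10, adjusted p = 0.054 with an estimated correlation), Tet1 by -0.35 (SE 0.05, adjusted p = 0.00017). Of 24 S phase genes edgeR called 0 higher and 0 lower (2 lower adjusted over the list alone, median -0.03), and camera's preset call (adjusted p = 0.014) was lost (adjusted p = 0.57 with an estimated correlation). Over all genes 430 were higher and 228 lower with si309. These counts were 242 and 133 without si308 replicate 0, 185 and 55 without si309 replicate 0, and 164 and 47 without si309 replicate 1, and the lower count was 136 without si308 replicate 1.

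Repeats were compared because MERVL, an endogenous retrovirus whose MT2_Mm repeat drives two-cell-like transcripts, is the reporter in these cells. MERVL-int rose 45.0-fold with Chaf1a siRNA, from 59.5 ± 0.15 to 2680 ± 110 CPM (5.49, SE 0.09), and fell to 73.6 ± 3.4 CPM with si308 (36.4-fold, log2 change -5.19, SE 0.08) and to 121 ± 3.8 CPM with si309 (22.1-fold, log2 change -4.47, SE 0.08), each with an adjusted p listed as 0. MT2_Mm rose 19.2-fold, from 33.7 ± 0.63 to 647 ± 19 CPM (4.26, SE 0.08), and stood at 35.8 ± 2.7 and 46.3 ± 0.64 CPM with the pools. The satellite GSAT_MM rose 33.5-fold to 9.8 ± 1.4 CPM (5.07, SE 0.24, adjusted p = 3.9e-96 in edgeR's test) and fell with si308 (-3.15) and si309 (-3.72, SE 0.19). Repeat p-values this small rest largely on a spread shared over repeats, not on that of each repeat between libraries. MERVL-int was higher with si309 than with si308 by 0.72 (SE 0.07, adjusted p = 1e-18) and MT2_Mm by 0.37 (SE 0.08, adjusted p = 0.0025), and MERVL-int stayed above the negative control with each pool (0.31 with adjusted p = 0.0011, and 1.03 with adjusted p = 4.1e-38).

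By list, Chaf1a siRNA raised 3 of 3 MERVL names (median 4.26), 4 of 5 other MT2 elements (0.48), 12 of 14 MaLR (0.41), 11 of 14 IAP with 2 lowered (0.46), 14 of 16 other ERV1 and ERVK elements (1) and 10 of 11 L1 (0.52). Adjusted over the list alone the counts were the same except for 14 MaLR and 12 IAP raised. With repeat-table scaling 7 MaLR names were raised and 1 lowered (0.18), and 5 IAP names were raised and 2 lowered (0.23). The medians of other MT2, other ERV1 and ERVK, and L1 names were 0.26, 0.78 and 0.30 with that scaling. Individual elements, picked outside the naming rule, were ORR1A0-int (91.4 to 469 CPM), B2_Mm1a (1.95), RLTR6-int (1.64) and IAP1-MM_I-int (-1.29). The lists of ETn and MusD (0 raised, 3 lowered; median -0.30), SINE (4 raised; 0.03) and satellites (1 raised, 1 lowered; 0.15) had medians of -0.52, -0.20 and -0.07 with repeat-table scaling, which changes the sign for SINE and satellites. With it 9 SINE names were lowered and 3 raised. Library totals went the other way, with 11 SINE names raised and 0 lowered (0.19). They gave 2 ETn and MusD names raised and 2 lowered (-0.13), and 1 satellite raised and 0 lowered (0.31). With gene-table scaling adjusted over the list alone, 3 ETn and MusD names were lowered, 3 SINE names raised, and 1 satellite raised and 1 lowered.

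With si308, 3 MERVL names, 4 other MT2, 9 MaLR, 8 IAP, 14 other ERV1 and ERVK, and 11 L1 names were lowered. With si309 these counts were 3, 4, 14, 9, 13 and 11. Repeat-table scaling changed the lowered MaLR names to 7 with si308 and 8 with si309 (medians from -0.28 to -0.11 and from -0.40 to -0.14), and the lowered IAP names to 4 and 6 (from -0.32 to -0.16 and from -0.43 to -0.17). With it other MT2 medians went from -0.44 to -0.28 and from -0.54 to -0.27, other ERV1 and ERVK medians from -0.62 to -0.45 and from -0.65 to -0.39, and L1 medians from -0.51 to -0.35 and from -0.70 to -0.43. Adjusted over the list alone the counts were 3, 4, 11, 10, 15 and 11 with si308 and 3, 5, 14, 9, 15 and 11 with si309. RLTR6-int returned to 30.4 and 29.5 CPM from 94.0 CPM, against 30.1 CPM in the negative control. B2_Mm1a stood at 1680 CPM with si308 and 1570 CPM with si309. ETn and MusD medians were -0.03 and -0.15 and SINE medians -0.05 and -0.14 with the pools, but 0.14 and 0.11, and 0.11 and 0.13, with repeat-table scaling. Satellite medians were -0.34 and -0.35, or -0.18 and -0.09 with that scaling. These calls were 1 and 2 lowered ETn and MusD names, 4 and 4 lowered SINE names and 1 and 1 lowered satellites, the same adjusted over the list alone. With repeat-table scaling 8 and 9 SINE names were raised and 2 and 2 lowered, and 3 and 1 ETn and MusD names were raised and 1 and 1 lowered. Between the pools only 2 MERVL names differed (2 raised adjusted over the list alone), and 1 IAP and 5 L1 names were lower with si309 adjusted over the list alone.

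**Figure D5:**
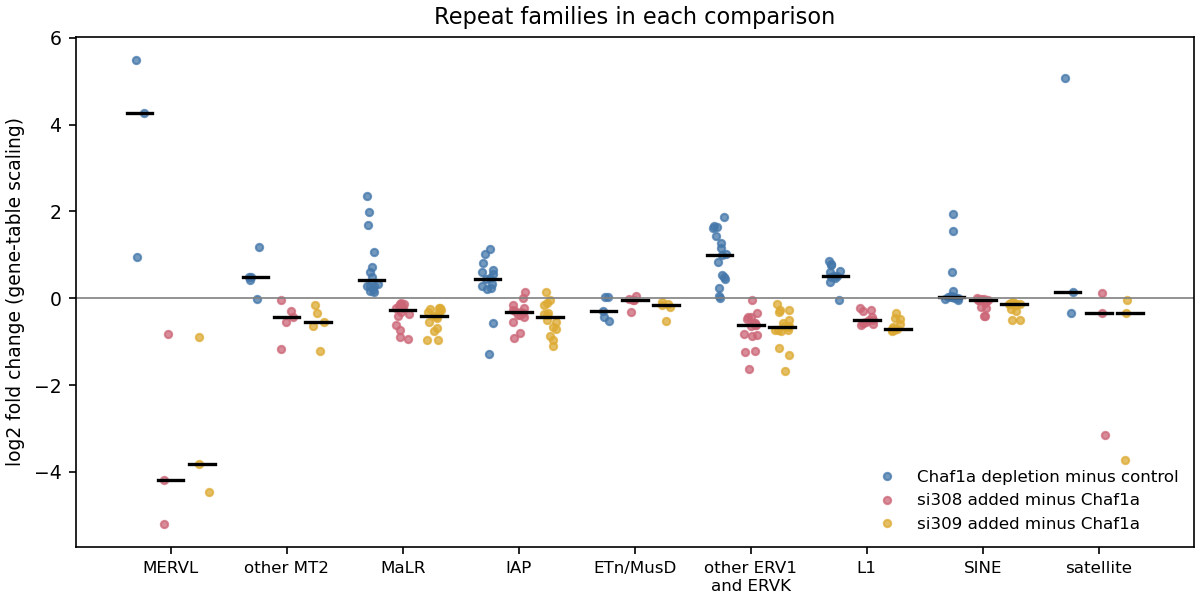
Log2 fold change of each tested repeat name (points) of the repeat lists for Chaf1a siRNA against the negative control and for each pool against the Chaf1a siRNA group, scaled with the gene table; black bars are medians. MERVL has a median of 4.26 after Chaf1a siRNA, and the SINE medians of 0.03, -0.05 and -0.14 become -0.20, 0.11 and 0.13 with repeat-table scaling, ETn and MusD changing sign for both pools and satellites for Chaf1a siRNA.

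Over all repeats 488 names rose and 39 fell with Chaf1a siRNA, 6 rose and 312 fell with si308, and 2 rose and 502 fell with si309. Repeat-table scaling moved the median of all repeats from 0.23 to 0, from -0.14 to 0.02 and from -0.25 to 0.01, and its counts were 288 and 232, 108 and 217, and 93 and 191. For Chaf1a siRNA the lowered count was 23 without Chaf1a siRNA replicate 0 and 59 without si308 replicate 1. The raised count for si308 was 3 and 17 without these libraries, and that for si309 was 1 without Chaf1a siRNA replicate 0, Chaf1a siRNA replicate 1 or si309 replicate 0. The lowered count was 507 for si308 without si308 replicate 0, and 317 and 331 for si309 without Chaf1a siRNA replicate 1 and without si309 replicate 0. Between the pools edgeR called 2 repeats higher and 0 lower with si309, while 123 had an unadjusted p under 0.05. The largest fitted rise with Chaf1a siRNA was of (GATTG)n (6.65, SE 1.41, adjusted p = 1.3e-05), at least 3.66-fold from no counts in the negative control. The short RNA repeat HY1 rose with Chaf1a siRNA (ratio 60.7, 10.5 to 2430) and was lower with si308 (25.8, 8.43 to 128) and si309 (24.5, 8.03 to 122). RLTR12F (3.69), RLTR41B (3.01) and IAPEY5_I-int (2.79) were further rises named by the rule, and (CATGT)n (-2.57) and (CAATA)n (-1.34) were among the falls.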

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

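The contrast between the pools was planned; the rule that picked single genes below and both tests of explanations were chosen after the results were seen.

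The pools differed beyond the spread between replicates, in edgeR's test of the difference itself. With si309, 430 genes were higher and 228 lower than with si308. These counts rest in part on single libraries: they were 242 and 133 without si308 replicate 0, 185 and 55 without si309 replicate 0, and 164 and 47 without si309 replicate 1, and the lower count was 136 without si308 replicate 1. Of the 430 genes, 385 had been raised by Chaf1a depletion and 31 were in the two-cell-like list, whose median difference was 3.65 (3.24 with bounds). Of the 228 genes, 157 had been lowered by Chaf1a depletion and 36 raised. MERVL-int was higher with si309 by 0.72 on the log2 scale (SE 0.07).

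Among named genes outside the two-cell-like list, at 1 CPM or more with either pool, the 5 largest differences each way were taken. In edgeR's test, those higher with si309 were Mgp (2.84, SE 0.43, adjusted p = 0.00035), S100a4 (2.28, SE 0.45, adjusted p = 0.0047), Scin (1.82, SE 0.38, adjusted p = 0.0068), KCTD12 (1.55, SE 0.16, adjusted p = 3e-06) and Actc1 (1.5, SE 0.32, adjusted p = 0.0095). S100a4 lost its call without si308 replicate 0 and without si309 replicate 1. Fits without a library covered only genes that the planned rule also named for this contrast, so they do not bear on the other genes here. KCTD12 was at 0.687 CPM in the negative control, 11.5 with Chaf1a siRNA, 1.79 with si308 and 5.24 with si309. By the same test, those lower with si309 were Gmnc (-1.62, SE 0.36, adjusted p = 0.01), Asb9 (-1.62, SE 0.39, adjusted p = 0.022), Lnx1 (-1.23, SE 0.31, adjusted p = 0.029), Spink10 (-1.12, SE 0.13, adjusted p = 1.8e-05) and Myb (-1.11, SE 0.20, adjusted p = 0.0021). Spink10 stood at 6.14 CPM with Chaf1a siRNA, 11.1 with si308 and 5.06 with si309, and Myb at 2.61, 4.27 and 2.00 CPM.

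The higher two-cell-like RNAs with si309 could come from deeper Chaf1a depletion in that arm or from more mDux RNA left. Against the former as the whole cause, the 3820 other genes raised at least 2-fold by Chaf1a depletion were higher with si309 by a median of 0.158, far below 3.65. The 95% bootstrap interval, 0.147 to 0.174, resamples genes and does not cover the spread between libraries. A smaller part for deeper Chaf1a depletion is not excluded (Chaf1a itself differed by -0.14, SE 0.07). More mDux RNA left with si309 stays open and is a candidate explanation: its counts were 5 and 9 against 1 and 4, with an unadjusted p = 0.043 and an adjusted p of 0.29. The counts are few, the locus has several copies, and a difference in other targets of the pools was not tested.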

How the results depend on the processing

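A minimum mean of 1 CPM and scaling by library totals were chosen after the data were seen; the other alternatives were planned. For single genes and repeats, 352 named results met 5209 alternatives. Of these 4877 kept their side of the threshold, 272 no longer passed and 60 newly passed, and 251 results kept their side throughout. Direction was compared only for results that passed in the main fit, and 0 of those reversed. DESeq2 kept 307 of 347, RLE scaling 318 of 321 and the fit without a filter 337 of 352. Column numbers were used as a block although it is unknown whether they pair libraries, and 341 of 352 kept their call.

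Requiring a change of at least 2-fold, which leaves fewer genes by construction, gave 3867 raised and 667 lowered genes for Chaf1a siRNA, 83 and 750 for si308, 29 and 544 for si309, 115 and 9 between the pools, 3332 and 411 for si308 against the negative control, and 3643 and 572 for si309. For repeats it gave 116 and 7, 1 and 48, and 1 and 59. Of Chaf1a-raised genes 710 were lowered by si308, 526 by si309 and 501 by both. With an estimated correlation camera called 1, 1, 1 and 1 lists in place of 12, 5, 4 and 9. Some lists that lost their call had an estimated correlation below the preset, so correlation alone does not account for the loss.

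For the rest the cause was not tested. DESeq2 gave 1089 genes raised with si308 and 419 with si309, 0 repeats raised with si308 and 0 with si309 (edgeR 6 and 2, with 416 and 610 repeats changed either way at unadjusted p under 0.05), and medians of Chaf1a-raised genes of -0.173 and -0.077. Fits of 2 groups only gave 1198 genes and 1 repeat raised with si309, and the replicate block 1 repeat. With no low-count filter 373 genes were lower between the pools, and the medians were -0.166 and -0.079. With library totals 7690 genes were raised and 3275 lowered with si308 against the negative control, and 8082 and 3556 with si309. Under that scaling Chaf1a siRNA raised 8128 genes and lowered 3788, 23 repeats were lowered by Chaf1a siRNA, and the medians were -0.105 and -0.035. At a mean of at least 1 CPM, 3 repeats were raised with si308 and 1 with si309, and the medians were -0.1 and -0.035. Scaling by the repeat table gave 288 raised and 232 lowered repeats for Chaf1a siRNA, 108 raised for si308, and 93 and 191 for si309, and it centres the median of repeats by construction.

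Leaving out 1 library at a time, where the lone library is assumed to vary like the other groups, gave 5959 to 6863 raised and 4877 to 5668 lowered genes for Chaf1a siRNA, 798 to 2051 and 1432 to 2419 for si308, 196 to 905 and 695 to 1474 for si309, and 164 to 567 and 47 to 326 between the pools. Against the negative control the ranges were 5186 to 5948 and 4631 to 5056 with si308, and 5600 to 6479 and 4769 to 5555 with si309. For repeats they were 353 to 555 and 23 to 59, 3 to 17 and 215 to 507, and 1 to 2 and 317 to 637. Chaf1a-raised genes lowered by si308 numbered 1199 to 1880, by si309 618 to 1086 and by both 602 to 1014, with medians of -0.182 to -0.141 and -0.095 to -0.064. Pseudocounts were not varied, since counts were fitted. In simulated data with 200 of 17977 genes changed, edgeR called 74% of genes changed by 1 on the log2 scale, so some changes of that size may be missed. Far more genes were called with Chaf1a siRNA, 6597 raised and 5545 lowered, so this share may not carry over. The 1254 genes under 0.1 CPM in the negative control have little room to fall.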

Other observations

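The family tests and the rule that forms families from gene names were chosen after the data were seen, as were the tests of weaker Chaf1a depletion, its simulated shares and the test of any diced pool; the tests of genomic DNA, scaling and shared libraries were set before their results.

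PolyA RNA of histone genes (Hist), not described above, was raised by Chaf1a siRNA and lowered by both pools in 10 of 29 cases (one-sided Fisher's exact test over 394 families, adjusted p = 9.7e-05). PolyA libraries do not measure histone RNA without a polyA tail. The family passed also within strata of the level in the negative control, where 2.5 genes were expected (exact Mantel-Haenszel test, adjusted p = 0.011). Both tests treat genes as independent and do not measure the spread between libraries. How reads shared between histone copies were counted is unknown. Hist1h4i stood at 1.02 CPM in the negative control, 5.41 with Chaf1a siRNA, 1.68 with si308 and 2.11 with si309. The Zscan family passed too (6 of 17, adjusted p = 0.0078, and 0.011 within strata), but 5 of the 6 are Zscan4 genes of the two-cell-like list. Protocadherins (Pcdh, 5 of 8, adjusted p = 0.0016) and olfactory receptors (Olfr, 6 of 20, adjusted p = 0.016) did not pass within strata (adjusted p = 0.2 and 0.65).

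In 13 other families some members rose at least 2-fold with Chaf1a siRNA and were lowered by neither pool more often than over all genes, but none of these families passed within strata of level (adjusted p from 0.62 to 1), so the low level of their genes in the negative control is not separated from the family. They were collagens (Col, 22 of 42, with 13.7 expected at their levels), Rhox (12 of 16, 7.8 expected), keratins (Krt, 14 of 25, 11.9 expected), kallikreins (Klk, 7 of 9, 4 expected), and the Cdh, Scn, Abca, Ly, Syt, Adcy, Muc, Gpr and Mmp families. Other members differ, such as Col1a2, which both pools lowered.

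Genes raised at least 2-fold by Chaf1a depletion outnumbered those lowered, 3867 to 667. In part this is because the filter admits genes near 0 in the negative control only if another group raises them. The numbers were 1526 and 102 at 0.1 to 1 CPM, where genes at the low end can pass the filter in the same way. At 1 to 10 CPM they were 905 and 259, and at 10 to 100 CPM 229 and 249. Genomic DNA in the depleted libraries was weighed with 299 olfactory and vomeronasal receptor genes under 1 CPM, whose mean rise per kb of exon was 0.027 of that of other protein-coding genes (0.015 to 0.043), so DNA is unlikely to be the source. Scaling was weighed with library totals, where the ratio of raised to lowered genes was 10.18, against 5.8 with TMM factors. Library totals moved the median of all genes up, from 0.05 to 0.22. The ratio could thus only rise, and it cannot show whether scaling contributed to the excess of raised genes. A direct effect of CAF-1 loss and a change in the mix of cell states remain open, and no biological explanation was tested.

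Of the 6597 genes raised by Chaf1a depletion, 926 were lowered by both mDux pools and 4782 by neither. In 20 simulations where the pools changed no gene, 0 such genes were lowered by both pools, so shared libraries alone did not give the 926. With no gene changed, adjusted p-values pass far less often than in the data. The simulations thus cannot show how much overlap sharing added beside effects of the pools. Weaker Chaf1a depletion in the pool arms is unlikely to be the whole cause for the two-cell-like list, which kept a median of 0% of its log2 rise with si308. Among its 41 genes with counts in the negative control the median was -4%. This reading takes the list and other raised genes to respond alike to the level of Chaf1a, which was not tested. Other raised genes kept a median share higher by 0.886 (95% bootstrap interval over genes 0.852 to 0.977), and with si309 the shares were 40.8% and 95.2%. For those other genes weaker Chaf1a depletion could contribute. The 667 genes lowered by Chaf1a depletion kept a share of 0.764 of their fall with si308 (interval over genes 0.749 to 0.787) and 87% with si309. Simulations without an effect of the pools gave 96.3% and 96.2%, and Chaf1a itself kept 89.8% and 96.1%. These bootstrap intervals do not cover the spread between libraries. An effect of any diced pool and an effect of losing mDux cannot be told apart here, as 0 groups had a diced pool against another sequence. Depletion of mDux remains open as a hypothesis, and both pools, made from separate fragments of the gene, lowered two-cell-like genes.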
